A study of Mus musculus with 23 samples.

How the data were processed

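RNA-seq was run on lungs of male Balb/c mice, with 1 library per mouse. Per the labels, mice breathed clean air or an aerosol of bacterial lipopolysaccharide (LPS, 0.21 mg/ml) for 10 min on each of 3 days. They received saline or human alpha1-antitrypsin (AAT, 4 mg/kg) into the peritoneum 1 h after each exposure, and lungs were taken 6 h after the last dose. AAT is a plasma protein that inhibits neutrophil elastase. It was given in its native form (nAAT), in an oxidized form (oxAAT) or as a recombinant protein (recAAT). The labels give 23 libraries in 5 groups: 3 from air, and 5 each from LPS, LPS+nAAT, LPS+oxAAT and LPS+recAAT. The labels speak of 5 mice per group. Only 3 air libraries and no mice given the AAT peptide C-36 were analysed here.

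The deposited file holds raw counts per Ensembl gene ID, with no normalization by the authors. Libraries were made with a stranded poly(A) kit, per the labels' protocols. Per the submitters' processing notes, the tools were FastQC 0.11.8, Trimmomatic 0.38 and 0.36, STAR 2.4.0.1 and HTSeq 0.11.1, with genome build GRCm38. Which libraries were trimmed with which Trimmomatic version, the strand setting of the counting and the annotation release are not given in the sources used here. The file holds 41388 genes and 5 summary lines, which were left out of library sizes and tests. Of all reads tallied, 6.79% to 13.13% fell on no annotated feature, 1.12% to 1.39% were ambiguous and 4.09% to 6.08% did not align uniquely. Gene symbols and positions were taken from GENCODE mouse release 21 (GRCm38), which named 40254 of the IDs and left 1134 without a symbol.

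The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, on the deposited counts of all 23 libraries in a single model with a mean per group and no covariate. Counts were scaled by TMM (factors 0.978 to 1.028), genes were filtered with filterByExpr by group, dispersions were robust, and p-values were adjusted with the Benjamini-Hochberg method. This left 17148 genes for each of 11 comparisons, and a gene was called at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes were derived from the fold change and its F statistic. CPM values are TMM-scaled counts relative to library size, given as mean ± SD over the mice of a group. P-values measure the spread between these mice. The depth was 14.8 to 47.9 M gene counts per library, with a median of 28.7 M, and counting error adds to the spread between mice, most for genes of a few CPM such as Cxcl2 and Areg.

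The comparisons, the tests, 40 gene lists, the rule for naming genes and the alternatives listed first here were fixed before the data were examined. Each list was tested against all other tested genes with camera of limma 3.58.1 (log2 CPM with a prior count of 2, trended variance, preset correlation 0.01, Benjamini-Hochberg over the lists of a comparison). The same test with an estimated correlation between genes, and the rotation test fry, were alternatives. Counts of list members are given over all genes tested and, in those words, adjusted over the list alone. For LPS vs air and for each AAT group against LPS, the named genes were the 8 largest log2 fold changes in each direction among called genes with an average log2 CPM of at least 1, groups whose libraries did not overlap in CPM, and a symbol other than a predicted gene or an immunoglobulin or T cell receptor segment. For the other comparisons the number was 4 per direction. Of the genes this rule names, 1 is not reported here. Where no gene passed in a direction, 3 genes of smallest p are given as values only. Up to 4 members of smallest adjusted p per list described, and a fixed panel of inflammatory genes, were added. Called genes of this rule were therefore higher, or lower, in every library of one group than in every library of the other.

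The alternatives fixed with the design were an adjusted p under 0.01, DESeq2 1.42.0 size factors in edgeR, library totals alone, no filter beyond 1 count, a stricter filter (CPM of at least 1 in at least 5 libraries), a dispersion that was not robust, the last digit of the mouse number as a block, 1 surrogate variable from sva 3.50.0, the DESeq2 Wald test, limma voom with sample quality weights, a fit of only the groups compared, and leaving out each library in turn. Chosen after seeing the data were a split of the libraries by the count of mt-Nd6 as a share of that of mt-Nd5 (above or below 2%), used as a term in the model or to select libraries, and an offset that removes from each library its curve of counts against transcript GC content (lowess, span 0.3). Mt-Nd6 is the mitochondrial protein gene on the opposite strand to the others, and its share rises with the share of reads counted on the wrong strand. As a check of the same property, 151 genes whose exons lie opposite well expressed genes (partner CPM of at least 50, at least 0.5 of their own exon length overlapping) were counted as detected at a CPM of 0.2.

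Replicates were compared before averaging. Over 43 pairs of libraries within groups, the chi-square of counts per degree of freedom was 5.78 to 79.49, which includes the differences between mice. Each step was tested on simulated counts of 17148 genes drawn with the real libraries' means and sizes. Of 100 genes changed 2-fold, the main test recovered 74 in LPS vs air, 79 in LPS+nAAT, 74 in LPS+oxAAT and 80 in LPS+recAAT against LPS. Of 100 genes changed 1.5-fold it recovered 41, 43, 56 and 41 in that order, with 3 to 9 false calls. With the library set as a term, it recovered 68 of 100 genes changed 2-fold and 27 of 100 changed 1.5-fold in LPS+oxAAT vs LPS, and 50 and 5 of 100 in LPS+recAAT vs LPS. Comparisons that share the LPS libraries were set beside values simulated with unchanged AAT groups (20 simulations) and values with the LPS libraries split in disjoint parts (20 splits).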

Results

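Lung gene expression was measured by RNA-seq in 23 male Balb/c mice, 1 library per mouse, at 17148 tested genes. The groups were clean air (n = 3), LPS (n = 5), LPS+nAAT (n = 5), LPS+oxAAT (n = 5) and LPS+recAAT (n = 5). Gene counts per library ran from 26.5 to 30.4 M in air, 19.7 to 33.8 M in LPS, 21.4 to 41.4 M in LPS+nAAT, 24.5 to 38 M in LPS+oxAAT and 14.8 to 47.9 M in LPS+recAAT. The first 2 principal components held 19% and 11.6% of the variance between libraries.

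The libraries fell into 2 sets that the labels do not name. In 15 libraries, called the first set here, the count of mt-Nd6, a mitochondrial gene on the opposite strand to its neighbours, was 0.34% to 1.14% of that of mt-Nd5. In 8 libraries, the second set, it was 3.39% to 4.5%. All air, LPS and LPS+nAAT libraries and LPS+oxAAT replicates 5101 and 5102 lay in the first set. LPS+oxAAT replicates 5103, 5104 and 5105 and all LPS+recAAT libraries lay in the second. Of 151 genes opposite well expressed genes, 20 to 27 were detected per library in the first set and 36 to 57 in the second. With AAT group held fixed, which rests on LPS+oxAAT replicates 5103 to 5105 against 5101 and 5102, the sets differed at 93 genes. Of these, 84 were higher and 9 lower in the second set. Exons of 40 of the 84 overlap, by any length, those of a gene on the other strand. That share was not counted over all tested genes, so the 40 alone do not show wrong-strand reads. Each comparison is therefore given over all libraries and, where it can be had, with the set as a term in the model or within a set. The first set holds no LPS+recAAT library, so LPS+recAAT is separated from the set only through the LPS+oxAAT libraries.

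**Figure D1:**
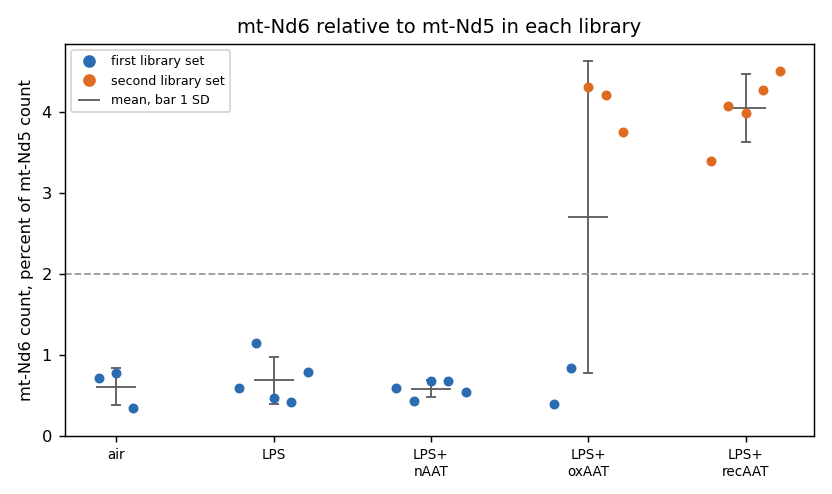
Count of mt-Nd6 as a percentage of the count of mt-Nd5 in each of the 23 libraries (y axis) by group (x axis). Points are libraries coloured by set, the horizontal mark and bar are the group mean and 1 SD, and the dashed line at 2% separates the sets, whose values run from 0.34% to 1.14% and from 3.39% to 4.5%.

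The comparison of LPS with air shows what repeated LPS inhalation did to the lung. Transcripts of neutrophil-attracting chemokines, acute phase proteins and the cell division machinery rose together. Saa3, an acute phase serum amyloid, went from 4.81 ± 1.17 CPM in air (SD, n = 3) to 286 ± 88.6 CPM in LPS (SD, n = 5), a 59.5-fold rise. Lcn2, an iron-binding antimicrobial protein, rose by 3.09 ± 0.17 on the log2 scale (SE; adjusted p = 8.21e-12). Of 17148 genes, 753 passed the test, 465 higher and 288 lower, and 181 of the higher but 27 of the lower changed at least 2-fold.

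Among the largest rises after LPS, ranked over genes whose groups did not overlap in CPM, were Cxcl3 (log2 fold change 4.90 ± 0.55 SE, adjusted p = 7.67e-06) and Cxcl5 (3.51 ± 0.51, 0.000132), which encode chemokines for neutrophils. Tnfrsf9, a costimulatory receptor of lymphocytes, rose by 4.32 ± 0.24 (8.21e-12). Acod1, the enzyme that makes itaconate in activated macrophages, rose by 3.21 ± 0.41 (1.21e-05), and Klk10, a secreted serine protease of the kallikrein family, by 3.19 ± 0.40 (1.84e-05). Lemd1 (4.28 ± 0.47) and Ly6i (3.43 ± 0.49) completed the 8 largest of these rises, and reads of Ly6i can be shared with close paralogs. The 8 largest falls among such genes were smaller. They were Arxes2 (-1.26 ± 0.26), Adh7, an alcohol dehydrogenase (-1.15 ± 0.30), the calcium pump gene Atp2b2 (-1.07 ± 0.19), the zinc finger genes Zfp984 (-1.07 ± 0.17), Zfp758 (-1.07 ± 0.21) and Zxdb (-1 ± 0.27), Aspn, a proteoglycan of the matrix (-1.03 ± 0.26), and Acaa1b, a peroxisomal thiolase (-0.98 ± 0.22). Arxes2 and Zfp984 have near-identical copies, so their counts are uncertain.

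Of 40 gene lists, 16 had a camera call between LPS and air, and 6 of these kept it with an estimated correlation. Of 17 tested inflammatory cytokines and chemokines, 13 rose and none fell after LPS (13 adjusted over the list alone; median log2 fold change 1.88, camera adjusted p = 8.7e-21), including Cxcl1 (2.03 ± 0.27), Ccl3 (2.30 ± 0.33) and Tnf (1.49 ± 0.26). Of 23 acute phase and secreted antimicrobial genes, 16 rose (18 adjusted over the list alone; median 1.29, 3.1e-30), among them Pigr, which carries IgA across epithelium (2.44 ± 0.24), and Chil1 (1.45 ± 0.13). Of 25 cell cycle genes, 23 rose (24 adjusted over the list alone; median 1.17, 5.5e-40), with Bub1b (1.38 ± 0.14), Mki67 (1.47 ± 0.16) and Cdk1 (1.17 ± 0.14). Of 19 targets and feedback genes of NF-kB, the inflammatory transcription factor, 10 rose (14 adjusted over the list alone; median 0.43, 3.3e-13), with Nfkb2 (0.66 ± 0.10) and Nfkbie (0.71 ± 0.11). Of 17 neutrophil proteases and protease inhibitors, 5 rose (7 higher and 1 lower adjusted over the list alone; median 0.24, 2e-05), of which Timp1 (1.48 ± 0.17), Serpina3n (1.20 ± 0.14) and Slpi (0.88 ± 0.14) encode inhibitors. Of 11 dendritic cell markers, 3 rose (4 adjusted over the list alone; median 0.07, 0.006), with the chemokine genes Ccl22 (1.33 ± 0.16) and Ccl17 (1.71 ± 0.24). With an estimated correlation these 6 lists had adjusted p from 0.00084 to 0.043.

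For 10 other lists the call after LPS was lost with an estimated correlation. Of 18 monocyte and recruited macrophage markers, 7 rose, and 8 adjusted over the list alone (adjusted p = 0.062 with an estimated correlation), with Cd14, the LPS co-receptor (2.23 ± 0.16), and C1qc (0.89 ± 0.13). Of 21 neutrophil markers, 3 rose, and 6 rose and 1 fell adjusted over the list alone (adjusted p = 0.12 with an estimated correlation), with Clec4d (1.37 ± 0.14) and Il1r2 (2.06 ± 0.34), while S100a8, an abundant neutrophil transcript, had 0.38 ± 0.37. Of 16 alveolar macrophage markers, 5 rose and 1 fell (7 and 3 adjusted over the list alone; adjusted p = 0.28 with an estimated correlation), with Marco, a scavenger receptor (2.60 ± 0.32). Of 20 interferon gamma induced genes, 3 rose (6 adjusted over the list alone; adjusted p = 0.34 with an estimated correlation), the chemokines Cxcl10 (1.88 ± 0.23), Cxcl9 (2 ± 0.43) and Cxcl11 (3.36 ± 0.88). Of 16 antigen presentation genes, 3 rose (10 adjusted over the list alone; adjusted p = 0.28 with an estimated correlation), and of 28 type I interferon genes, 1 rose (5 adjusted over the list alone; adjusted p = 0.48 with an estimated correlation), Isg15 (1.09 ± 0.27). Of 15 cholesterol and fatty acid synthesis genes, 4 fell (9 lower and 1 higher adjusted over the list alone; median -0.30, adjusted p = 0.28 with an estimated correlation), with Insig1 (-0.81 ± 0.11). Of 16 xenobiotic metabolism genes, 2 fell (3 adjusted over the list alone; adjusted p = 0.43 with an estimated correlation). Of 8 liver secreted proteins, 1 fell (4 adjusted over the list alone; median -1.87, adjusted p = 0.58 with an estimated correlation), and none of 20 ribosomal protein genes passed, whether over all genes or adjusted over the list alone (median 0.19, adjusted p = 0.61 with an estimated correlation).

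In the first set alone, 543 genes passed between LPS and air, 370 higher and 173 lower. A fit of only these 2 groups gave 354 (268 and 86), and the last digit of the mouse number as a block gave 1364 (655 and 709), where higher calls were no longer in excess. The count fell to 473, 391 and 420 without air replicates 2101, 2102 and 2105. The call of Adh7 was lost without air replicates 2102 (adjusted p = 0.251) and 2105 (0.0812) and LPS replicates 1101 (0.0515), 1102 (0.0505) and 1104 (0.0536). That of Aspn was lost without air replicates 2101 (0.0816) and 2105 (0.0899) and LPS replicate 1101 (0.0545), and that of Acaa1b without air replicate 2101 (0.0849). Isg15 (0.109 without air replicate 2101), Cxcl9 (0.0557 without air replicate 2105) and Cxcl11 (0.146 without air replicate 2102) also lost their call. Zxdb was lost without any of the 3 air replicates or LPS replicates 1101, 1102 and 1104, at up to 0.14 without air replicate 2101. Adh7 (adjusted p = 0.0603) and Aspn (0.144) did not pass with the GC curve removed. Zfp984 and Zfp758 passed there at smaller log2 fold changes of -0.68 and -0.64. Arxes2 (-1.15), Atp2b2 (-1.14), Zxdb (-1.01) and Acaa1b (-1.12) moved less.

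**Figure D2:**
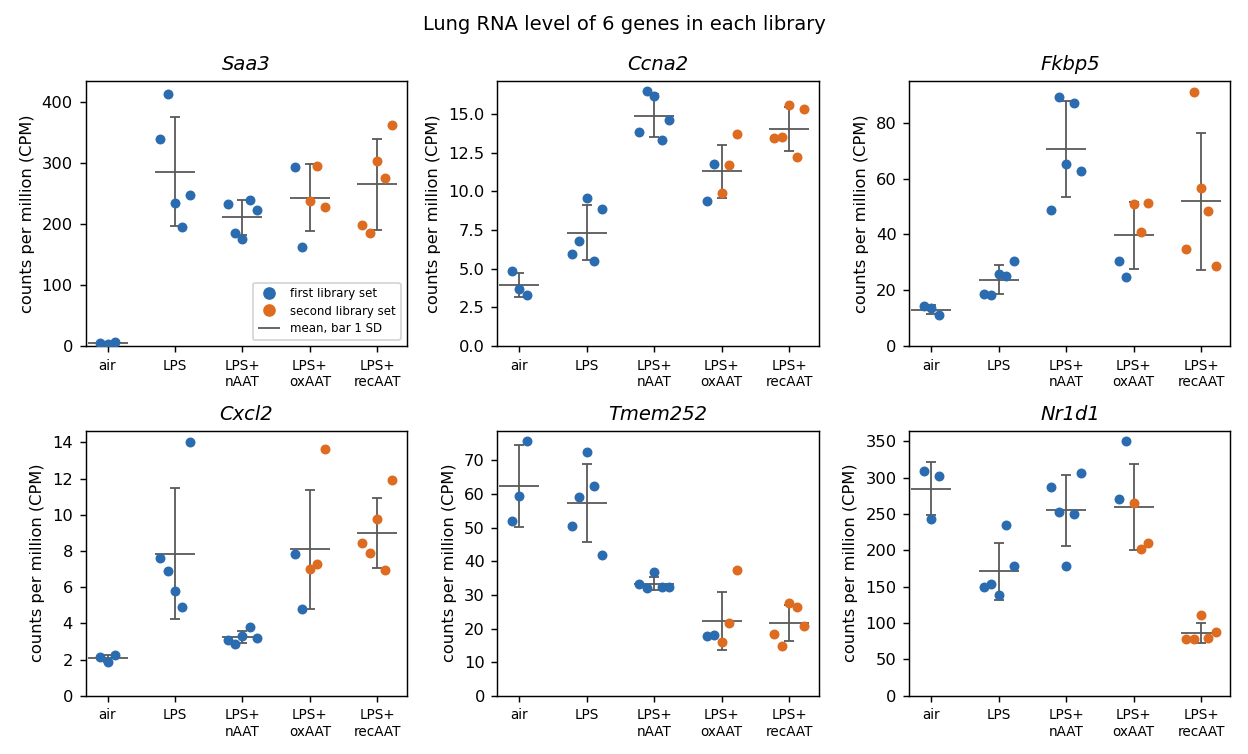
Level of 6 genes in each library, in CPM (y axis, from 0), by group (x axis), with points coloured by library set and marks and bars for the group mean and 1 SD. Saa3 averaged 4.81 CPM in air and 286 CPM in LPS, Cxcl2 was lower in every LPS+nAAT library than in every LPS library, and Nr1d1 averaged 86.8 CPM in LPS+recAAT and 260 CPM in LPS+oxAAT.

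The comparison of LPS+nAAT with LPS asks what the native protein did in LPS-exposed lungs, and all its libraries lie in the first set. Cell cycle genes were higher, as were Fkbp5 and Zbtb16, while the chemokine Cxcl2 and some immediate early genes were lower. Fkbp5, a chaperone partner of the glucocorticoid receptor, went from 23.7 ± 5.19 CPM in LPS to 70.6 ± 17.2 CPM in LPS+nAAT (SD, n = 5 each). Zbtb16, a zinc finger factor induced by glucocorticoids, went from 22.9 ± 20 to 206 ± 50.9 CPM. Cxcl2, a chemokine for neutrophils, went from 7.86 ± 3.61 to 3.24 ± 0.35 CPM, against 2.07 ± 0.197 CPM in air (n = 3). In all, 102 genes passed, 77 higher and 25 lower.

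Over genes whose groups did not overlap in CPM, the 8 largest rises with nAAT were Zbtb16 (log2 fold change 3.17 ± 0.61 SE, adjusted p = 0.0262), Fkbp5 (1.57 ± 0.27, 0.0101), Hif3a, a hypoxia-inducible factor subunit (1.44 ± 0.32, 0.0367), the cyclins Ccna2 (1.02 ± 0.14, 0.00138) and Ccnb1 (0.95 ± 0.17, 0.0101), the transcription factor Klf10 (0.94 ± 0.12, 0.000606), Tmem117 (0.91 ± 0.20, 0.0338) and Pclaf, a partner of the replication clamp PCNA (0.81 ± 0.19, 0.0391). The 8 largest falls of such genes were Cxcl2 (-1.28 ± 0.25, 0.0186), Zfp36, whose protein destabilises inflammatory mRNAs such as that of Tnf (-1.14 ± 0.14, 0.000349), Csrnp1 (-1 ± 0.21, 0.0278), Klf2, a transcription factor of the endothelium (-0.84 ± 0.16, 0.0148), Carmil3 (-0.81 ± 0.15, 0.0112), Ankrd55 (-0.77 ± 0.17, 0.033), Spry4, an inhibitor of growth factor receptor signalling (-0.77 ± 0.13, 0.00773), and Rai2 (-0.69 ± 0.12, 0.0101). The LPS-induced genes Saa3 (-0.44 ± 0.20), Lcn2 (-0.06 ± 0.13), Il1b (0.13 ± 0.19), Tnf (-0.40 ± 0.21), Cxcl1 (-0.85 ± 0.21, adjusted p = 0.0585) and Cxcl5 (-0.68 ± 0.34) did not pass.

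Of 25 cell cycle genes, 15 rose with nAAT and none fell (22 adjusted over the list alone; median 0.64, camera adjusted p = 4.2e-27, and 0.021 with an estimated correlation), including Rrm2, a subunit of ribonucleotide reductase (0.70 ± 0.11), and the spindle gene Tpx2 (0.64 ± 0.12). In the first set alone 3 of them passed, with a median of 0.63 (adjusted p = 0.061 with an estimated correlation). Of 16 immediate early and heat shock genes, 3 fell (7 adjusted over the list alone; median -0.29, camera adjusted p = 6.7e-06, and 0.021 with an estimated correlation): Zfp36, the phosphatase gene Dusp1 (-0.70 ± 0.15) and Fos (-0.65 ± 0.14). That adjusted p was 0.061 in the first set alone and 0.082 with the GC curve removed. Of 19 NF-kB targets and feedback genes, 1 fell (6 adjusted over the list alone; median -0.14, camera adjusted p = 2.9e-06, and 0.024 with an estimated correlation), Tnfaip3, a feedback inhibitor (-0.32 ± 0.07). In the first set alone this was adjusted p = 0.11 with an estimated correlation. None of 16 alveolar macrophage markers passed over all genes, but 8 were higher adjusted over the list alone (median 0.36, camera adjusted p = 3.6e-07, and adjusted p = 0.12 with an estimated correlation). Of 12 glucocorticoid responsive genes, Fkbp5 and Zbtb16 rose and Dusp1 fell (2 higher and 4 lower adjusted over the list alone; median -0.11, camera adjusted p = 0.57).

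The other calls with nAAT were lost with an estimated correlation. They were the inflammatory cytokines and chemokines, with 1 of 17 lower (2 adjusted over the list alone; median -0.40, adjusted p = 0.74 with an estimated correlation), and the neutrophil markers, with 1 of 21 higher (4 adjusted over the list alone; median 0.45, adjusted p = 0.66 with an estimated correlation), Fpr2 (0.49 ± 0.11). None of 12 B cell markers passed, nor did any adjusted over the list alone (median -0.31, adjusted p = 0.75 with an estimated correlation), and the same held for 10 heart muscle markers (median -0.73, adjusted p = 0.75 with an estimated correlation). None of 14 alveolar type 2 markers passed (3 adjusted over the list alone; median 0.14, adjusted p = 0.74 with an estimated correlation) and none of 12 alveolar type 1 markers (1 adjusted over the list alone; median 0.16, adjusted p = 0.49 with an estimated correlation).

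The number of genes called between LPS+nAAT and LPS moved with single libraries and with the fit. It was 34 in the first set alone (20 higher, 14 lower), 196 with the set as a term, and 42, 30, 20, 32 and 27 without LPS replicates 1101, 1102 and 1104 and LPS+nAAT replicates 4103 and 4104. Zbtb16 (up to adjusted p = 0.0939), Hif3a (0.0962), Tmem117 (0.0962), Pclaf (0.14), Csrnp1 (0.101), Ankrd55 (0.0903), Dusp1 (0.101), Fos (0.123), Tnfaip3 (0.13) and Fpr2 (0.14) lost their call without any of 5 to 8 of the 10 libraries, LPS replicate 1104 or LPS+nAAT replicate 4104 giving the highest value. The camera call of the cytokine list was lost without LPS replicate 1105 (adjusted p = 0.34) and that of the neutrophil markers without LPS+nAAT replicate 4102 (0.113). Cxcl2 lost its call without LPS+nAAT replicate 4103 (0.0522), Klf2 without LPS+nAAT replicate 4104 (0.0545) and Tpx2 without LPS replicate 1102 (0.0537). In the first set alone Zbtb16 (log2 fold change 3.16, adjusted p = 0.0523), Tmem117 (0.90, 0.0762) and Ankrd55 (-0.78, 0.0763) did not pass, at nearly the same changes as over all libraries. With the GC curve removed Tmem117 (0.76, 0.069), Pclaf (0.66, 0.12) and Csrnp1 (-0.85, 0.0955) did not pass.

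**Figure D3:**
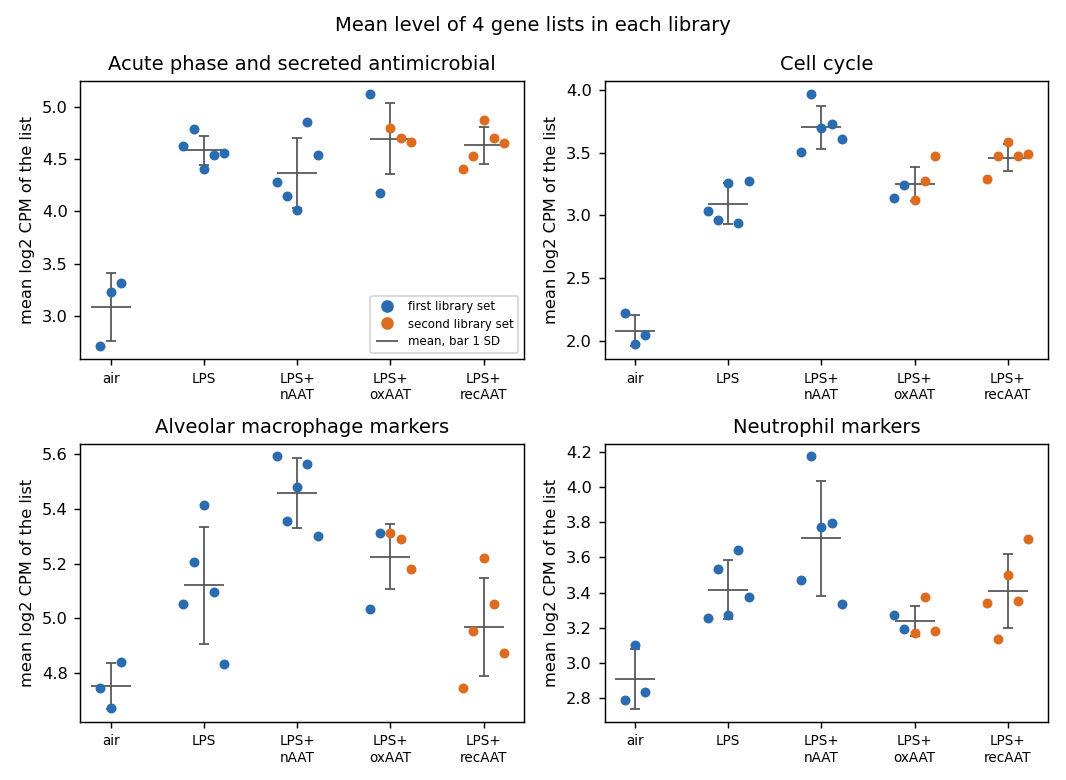
Mean log2 CPM of 4 gene lists in each library (y axis) by group (x axis), with points coloured by library set and marks and bars for the group mean and 1 SD. The cell cycle list was lowest in air and highest in LPS+nAAT, with a median log2 fold change of 1.17 for LPS vs air and 0.64 for LPS+nAAT vs LPS.

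The comparison of LPS+oxAAT with LPS asks the same of the oxidized protein, of which 3 of 5 libraries lie in the second set. Within the first set, where 2 LPS+oxAAT libraries can be set against all 5 of LPS, the genes Per1 and Tmem252 were lower. Over all libraries of both sets, Per1, a repressor of the circadian clock that also responds to glucocorticoids, went from 240 ± 34.3 to 106 ± 33.1 CPM (SD, n = 5 each). Tmem252 went from 57.3 ± 11.6 to 22.2 ± 8.77 CPM over the same libraries. In all, 808 genes passed, 676 higher and 132 lower, over all libraries, but 6 passed with the set as a term (2 higher, 4 lower) and 13 in the first set alone (4 higher, 9 lower). A fit of only the LPS and LPS+oxAAT libraries called 15 (9 higher, 6 lower), the DESeq2 Wald test 1255 and voom 1688.

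Among the largest falls with oxAAT of genes whose groups did not overlap in CPM were Tmem252 (log2 fold change -1.37 ± 0.20 SE, adjusted p = 0.000769), Cebpd, a transcription factor of inflammation (-1.22 ± 0.22, 0.00427), Csrnp1 (-1.21 ± 0.21, 0.00311), Per1 (-1.18 ± 0.19, 0.00161), Irx1 (-0.92 ± 0.18, 0.00688), Errfi1, a feedback inhibitor of the EGF receptor (-0.86 ± 0.15, 0.00376), and Rgcc (-0.73 ± 0.20, 0.0351). With the set as a term, Tmem252 (-1.67, 0.0127) and Per1 (-1.54, 0.0127) still passed. In the first set alone, Tmem252 (0.000354), Per1 (0.000354), Irx1 (0.0158) and Errfi1 (0.016) passed. The largest rises of such genes were Prrg1 (1.5 ± 0.23), Snhg14 (1.49 ± 0.34), Gt(ROSA)26Sor (1.46 ± 0.25), Zfp992 (1.30 ± 0.26), Rab3c (1.19 ± 0.30), Vma21, an assembly factor of the vacuolar proton pump (1.12 ± 0.17), Bmt2 (1.07 ± 0.16) and Lipo3 (1.04 ± 0.15). None of these 8 passed with the set as a term, at 0.50 to 1.18. Snhg14 and Gt(ROSA)26Sor are non-coding genes that overlap others on the opposite strand, and their counts are uncertain, as are those of Zfp992, which has near-identical copies.

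No list kept its call between LPS+oxAAT and LPS with an estimated correlation. Of 10 mitochondrially encoded genes, 2 rose, mt-Nd2 and mt-Nd6, and 3 rose adjusted over the list alone. The median of the list was 0.54 (camera adjusted p = 0.0043, and adjusted p = 0.96 with an estimated correlation), and 0.07 with the GC curve removed. The count of mt-Nd6 also defines the library sets. Without any of 8 of the 10 libraries mt-Nd2 lost its call, and mt-Nd6 without any of 3. Of 8 liver secreted proteins, 1 rose (6 adjusted over the list alone; median 1.84, camera adjusted p = 0.0066, and adjusted p = 0.96 with an estimated correlation), albumin (Alb, 1.78 ± 0.51). Of 19 NF-kB genes, 1 fell (2 adjusted over the list alone; adjusted p = 0.96 with an estimated correlation), Nfkbia, the NF-kB inhibitor (-0.49 ± 0.10), and of 28 type I interferon genes, 1 rose (1 adjusted over the list alone; adjusted p = 0.96 with an estimated correlation). None of 16 antigen presentation genes passed, nor adjusted over the list alone (median -0.18, adjusted p = 0.96 with an estimated correlation), and none of 20 ribosomal protein genes (1 lower adjusted over the list alone; median -0.21, adjusted p = 0.96 with an estimated correlation). The LPS-induced genes Saa3 (-0.23 ± 0.20), Lcn2 (-0.07 ± 0.13), Cxcl1 (0.01 ± 0.21), Cxcl2 (0.04 ± 0.24), Cxcl5 (0.60 ± 0.33), Il1b (0.13 ± 0.19) and Tnf (0.02 ± 0.20) did not pass. Zbtb16 rose by 2.56 ± 0.60 over all libraries.

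With the GC curve removed, 233 genes passed between LPS+oxAAT and LPS, 147 higher and 86 lower, so that the share of higher calls went from 83.7% to 63.1%. Irx1 (adjusted p = 0.0565), Rgcc (0.138), Snhg14 (0.125), Zfp992 (0.1) and Rab3c (0.0942) did not pass there. The count was 388, 234, 305, 167, 342 and 416 without LPS replicates 1101, 1102 and 1104 and LPS+oxAAT replicates 5103, 5104 and 5105, but 1552 and 1881 without LPS replicate 1105 and LPS+oxAAT replicate 5102. Rab3c (up to adjusted p = 0.0777), Rgcc (0.135) and Alb (0.166) lost their call without any of 6 or 7 of the 10 libraries, the highest values coming without LPS replicate 1102 or LPS+oxAAT replicate 5103. Snhg14 lost it without LPS+oxAAT replicate 5103 (0.0663).

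The comparison of LPS+recAAT with LPS concerns the recombinant protein, and all its 5 libraries lie in the second set while all 5 of LPS lie in the first. Over all libraries, Csrnp1, Areg and some immediate early genes were lower, and the chemokine Cxcl5 and some cell cycle genes were higher. Csrnp1 went from 47.2 ± 14.2 to 19.2 ± 4.3 CPM, Areg, which encodes the EGF receptor ligand amphiregulin, from 3.49 ± 0.89 to 1.35 ± 0.434 CPM, and Cxcl5 from 7.7 ± 2.51 to 24.9 ± 12.4 CPM (SD, n = 5 each). In all, 1456 genes passed, 1110 higher and 346 lower. Also without the set in the model, the DESeq2 Wald test called 1930 and voom with quality weights 2038. With the set as a term edgeR called 0 genes (1261 at an unadjusted p under 0.05), and DESeq2 and voom were not run with it.

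The largest falls with recAAT of genes whose groups did not overlap in CPM were Tmem252 (log2 fold change -1.42 ± 0.20 SE, adjusted p = 0.000338), Areg (-1.38 ± 0.30, 0.00509), Csrnp1 (-1.31 ± 0.21, 0.000832), Spon2 (-1.16 ± 0.30, 0.0146), Syt6 (-1.01 ± 0.23, 0.00652), the clock repressor gene Nr1d1 (-0.98 ± 0.16, 0.000848), Klf2 (-0.91 ± 0.16, 0.00111) and Zfp36 (-0.90 ± 0.14, 0.000665). These were, with the set as a term, -1.90, -1.79, -1.67, -0.67, -0.75, -0.52, -1.06 and -0.44, and none passed. The largest rises of such genes were mt-Nd6 (3.35 ± 0.60) and Syn3 (2.86 ± 0.48), which went to 0.13 and -0.25 with the set as a term, then Snhg14 (1.98 ± 0.33), Gt(ROSA)26Sor (1.85 ± 0.25), Rab3c (1.76 ± 0.30), Cxcl5 (1.71 ± 0.33), Prrg1 (1.60 ± 0.23) and the cyclin Ccne2 (1.49 ± 0.26). These 6 were 0.48 to 1.31 with the set as a term. Syn3, mt-Nd6, Snhg14 and Gt(ROSA)26Sor overlap genes on the opposite strand, and their counts are uncertain.

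No list kept its call between LPS+recAAT and LPS with an estimated correlation. Of 25 cell cycle genes, 5 rose (9 adjusted over the list alone; median 0.33, camera adjusted p = 1.2e-06, and adjusted p = 0.9 with an estimated correlation), with Ccna2 (0.93 ± 0.15) and Ccnb1 (0.93 ± 0.17); the median was 0.21 with the set as a term. Of 10 mitochondrially encoded genes, 5 rose, and 7 adjusted over the list alone. Among the 5 was mt-Nd6, whose count also defines the library sets. The median of the list was 0.74 (camera adjusted p = 5.6e-06, and adjusted p = 0.9 with an estimated correlation), and 0.18 with the GC curve removed. Of 16 immediate early and heat shock genes, 4 fell (4 adjusted over the list alone; median -0.19, camera adjusted p = 0.04, and adjusted p = 0.9 with an estimated correlation), with Dusp1 (-0.65 ± 0.15). Of 12 B cell markers, 1 fell (2 adjusted over the list alone; median -0.39, camera adjusted p = 0.0037, and adjusted p = 0.97 with an estimated correlation), and the median was 0.41 with the set as a term. None of 16 antigen presentation genes passed, nor adjusted over the list alone (median -0.24, adjusted p = 0.97 with an estimated correlation). Of 12 glucocorticoid responsive genes, 2 rose and 3 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.39): Fkbp5 (1.12 ± 0.27) and Zbtb16 (2.13 ± 0.59) rose, and Errfi1 (-0.88 ± 0.15), Per1 (-0.85 ± 0.19) and Dusp1 fell. The LPS-induced genes Saa3 (-0.11 ± 0.20), Lcn2 (0.16 ± 0.13), Cxcl1 (0.39 ± 0.21), Il1b (0.29 ± 0.19) and Tnf (0.21 ± 0.20) did not pass.

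With the GC curve removed, 688 genes passed between LPS+recAAT and LPS, 376 higher and 312 lower, so that the share of higher calls went from 76.2% to 54.7%. The count was 963, 923, 865 and 2316 without LPS replicates 1101, 1102, 1104 and 1105.

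**Figure D4:**
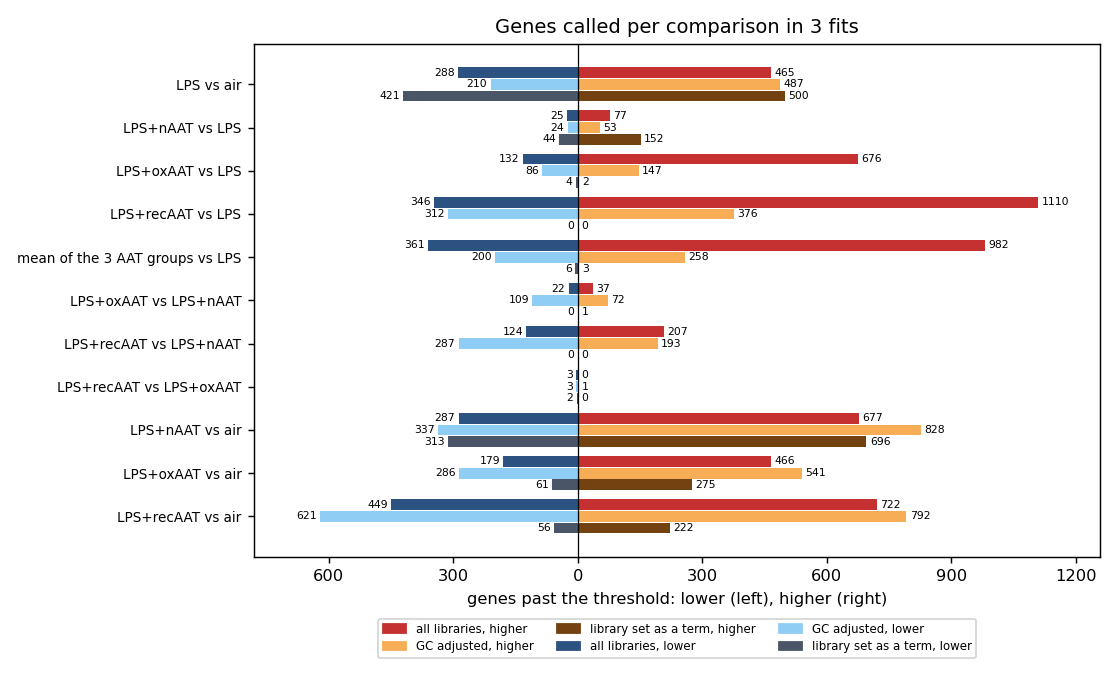
Genes past the threshold in each of 11 comparisons (y axis), with lower genes to the left of 0 and higher genes to the right (x axis, number of genes), in 3 fits. For LPS+recAAT vs LPS the bars show 1110 higher and 346 lower over all libraries, 376 and 312 with the GC curve removed, and 0 with the library set as a term.

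The mean of the 3 AAT groups against LPS asks what changed on average over the preparations. A gene can pass this test without a change in each of the 3 groups. Klf10 (log2 fold change 1.01 ± 0.11 SE, adjusted p = 9.16e-06) and Klf11 (0.80 ± 0.10, 8.22e-05), both Kruppel-like transcription factors, were higher, and Tmem252 (-1.19 ± 0.15, 0.000134), Csrnp1 (-1.17 ± 0.16, 0.000421) and Per1 (-0.87 ± 0.14, 0.0017) were lower. These 5 also passed with the set as a term, at 0.94, 0.79, -1.45, -1.37 and -1.17. The set is estimated from LPS+oxAAT alone. Its 2 first-set libraries therefore enter the LPS+oxAAT change and, through the set, the LPS+recAAT change. They weigh most among the AAT libraries in that fit, so passing it does not show a change with each preparation. Mbnl1 (0.72 ± 0.12), Pclaf (0.72 ± 0.16) and Errfi1 (-0.75 ± 0.12) passed over all libraries but not with the term. There Mbnl1 (0.38, adjusted p = 0.363) and Pclaf (0.44, 0.577) changed less, while Errfi1 (-0.87, 0.0623) did not. Pclaf also did not pass with the GC curve removed (0.117). Of all genes, 1343 passed (982 higher, 361 lower), and 9 with the set as a term (3 higher, 6 lower). There were 458, 258 of them higher, with the GC curve removed, and the share of higher calls went from 73.1% to 56.3%. The count was 620, 416, 410, 2262 and 2097 without LPS replicates 1101, 1102, 1104 and 1105 and LPS+oxAAT replicate 5102.

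The preparations were also compared directly, since a gene called with one and not with another does not show a difference. Between LPS+recAAT and LPS+oxAAT, 3 genes passed, all lower with recAAT: Nr1d1 (log2 fold change -1.58 ± 0.16 SE, adjusted p = 1.48e-05), Dbp, a clock output factor (-0.95 ± 0.17, 0.0366), and Igfbp3, a binding protein of insulin-like growth factors (-0.81 ± 0.10, 0.00022). Within the second set, which holds 3 LPS+oxAAT and all 5 LPS+recAAT libraries, Nr1d1 (-1.38, 0.000805) and Igfbp3 (-0.76, 0.00459) passed and Dbp did not (-0.70, 0.378). Dbp lost its call without any of 7 of the 10 libraries, at up to adjusted p = 0.183 without LPS+recAAT replicate 6102. No gene was called higher with recAAT in the main edgeR fit (497 genes in both directions at an unadjusted p under 0.05). The smallest p of a higher gene there belonged to Sh3d21 (0.61 ± 0.12), Spaar (0.49 ± 0.10) and Fbxo5 (0.52 ± 0.11), each at an adjusted p of 0.19. Other fits called some higher: 5 by the DESeq2 Wald test and 3 by voom. In edgeR they were 2 within the second set, 2 with the last digit of the mouse number as a block, 1 with the GC curve removed and 1 without LPS+oxAAT replicate 5105. The lists of cell cycle genes (median 0.19) and alveolar macrophage markers (median -0.24) had adjusted p = 0.26 and 0.23 with an estimated correlation.

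Between LPS+oxAAT and LPS+nAAT, 59 genes passed, 37 higher and 22 lower with oxAAT. Alb (log2 fold change 2.41 ± 0.53 SE, adjusted p = 0.0495), Cxcl2 (1.32 ± 0.25, 0.0262), Prrg1 (1.23 ± 0.23, 0.0262) and Sox4 (0.86 ± 0.16, 0.0262) were higher. The neutrophil transcript S100a9 (-1.59 ± 0.31, 0.0373), Rgcc (-0.98 ± 0.20, 0.0373), Tent5b (-0.90 ± 0.18, 0.0373) and Bcl2l1, a survival factor (-0.72 ± 0.12, 0.00918), were lower. Of 25 cell cycle genes, 1 was lower (24 adjusted over the list alone; median -0.49, adjusted p = 0.068 with an estimated correlation), and of 21 neutrophil markers, 3 (10 adjusted over the list alone; median -0.54, adjusted p = 0.068 with an estimated correlation). None of the 8 named genes passed in the first set alone, where 2 genes passed, or with the set as a term, where 1 did. With the term the log2 fold changes of Alb, Cxcl2, Prrg1 and Sox4 were 2.71, 0.96, 0.47 and 0.60. Those of S100a9, Rgcc, Tent5b and Bcl2l1 were -1.35, -1.17, -0.93 and -0.84, so a lost call was not always a smaller change. There were 181, 72 higher and 109 lower, with the GC curve removed, and the share of higher calls went from 62.7% to 39.8%. The count was 19, 6, 5, 4 and 24 without LPS+nAAT replicates 4101 to 4105 in turn, and 275, 5 and 3 without LPS+oxAAT replicates 5102, 5103 and 5104. Of the 8 named genes only Bcl2l1 kept its call with each library left out, and the others reached adjusted p from 0.0873 to 0.167, at LPS+oxAAT replicate 5103 for all but Cxcl2, which did so without LPS+nAAT replicate 4102.

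Between LPS+recAAT and LPS+nAAT, 331 genes passed, 207 higher and 124 lower with recAAT. Also without the set in the model, DESeq2 called 602 and voom 1523. With the set as a term none passed in edgeR (2093 at an unadjusted p under 0.05), and DESeq2 and voom were not run with it. Higher over all libraries were the chemokine genes Cxcl5 (log2 fold change 2.39 ± 0.34 SE, adjusted p = 0.00202), Cxcl1 (1.24 ± 0.21, 0.00425) and Cxcl2 (1.48 ± 0.25, 0.00425). Nr1d1 (-1.56 ± 0.16, 2.04e-05), Cilp, a matrix protein gene (-1.13 ± 0.23, 0.0135), Tex11 (-1.06 ± 0.21, 0.01) and Acoxl (-0.97 ± 0.17, 0.00425) were lower. The genes mt-Nd6 (3.33 ± 0.60), Syn3 (2.83 ± 0.48) and Snhg14 (1.58 ± 0.32), each overlapping another on the opposite strand, were higher, and Snhg14 lost its call without LPS+recAAT replicate 6101 (adjusted p = 0.0627). Cxcl5 was 1.63 (adjusted p = 0.324) and Nr1d1 -1.09 (0.315) with the set as a term. Of 16 alveolar macrophage markers, 7 were lower (12 adjusted over the list alone; median -0.52, adjusted p = 0.058 with an estimated correlation), and of 17 cytokines and chemokines, 4 were higher (7 adjusted over the list alone; median 0.58, adjusted p = 0.18 with an estimated correlation). With the GC curve removed 480 genes passed, 193 higher and 287 lower, and the share of higher calls went from 62.5% to 40.2%. The count was 186, 173, 153 and 138 without LPS+nAAT replicates 4101, 4102, 4104 and 4105, and 88 and 150 without LPS+recAAT replicates 6101 and 6104.

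Every AAT group still differed from air. Saa3 was higher by 5.46 ± 0.32, 5.66 ± 0.32 and 5.79 ± 0.32 on the log2 scale (SE) in LPS+nAAT, LPS+oxAAT and LPS+recAAT, and Cxcl3 by 4.34 ± 0.54, 5.14 ± 0.55 and 5.87 ± 0.56. Tnfrsf9 was higher by 4.31, 4.70 and 4.91 in that order, Zbtb16 by 4.53 ± 0.83 in LPS+nAAT, Lemd1 by 4.28 ± 0.47 in LPS+oxAAT and Cxcl5 by 5.21 ± 0.53 in LPS+recAAT. Mfsd2a, a lipid transporter, was lower by log2 fold changes of -1.86 ± 0.34, -2.23 ± 0.34 and -2.34 ± 0.35. Cyp26b1, which degrades retinoic acid (-2.57 ± 0.65), and Atp2b2 (-1.56 ± 0.19) were lower in LPS+nAAT, and the immediate early gene Nr4a1 in LPS+nAAT (-1.49 ± 0.25) and LPS+recAAT (-1.60 ± 0.25). Ces1f (-1.33 ± 0.26), Tmem252 (-1.49 ± 0.22) and Csrnp1 (-1.45 ± 0.23) were lower in LPS+oxAAT, and Areg (-1.78 ± 0.33) and Nr1d1 (-1.72 ± 0.18) in LPS+recAAT. In all, 964 genes passed in LPS+nAAT (677 higher, 287 lower), 645 in LPS+oxAAT (466 and 179) and 1171 in LPS+recAAT (722 and 449). Within the first set these were 798 for LPS+nAAT and 251 for LPS+oxAAT, and with the set as a term 336 for LPS+oxAAT and 278 for LPS+recAAT. Without air replicate 2105 the counts were 392 in LPS+oxAAT and 762 in LPS+recAAT. Cyp26b1 lost its call without air replicates 2101 (adjusted p = 0.0758) and 2102 (0.0899) and in the first set alone (0.0561). Mfsd2a (0.144) and Nr4a1 (0.174) did not pass in LPS+recAAT with the set as a term, and in the first set alone Ces1f (0.0667) did not pass in LPS+oxAAT.

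Whether AAT moved LPS-responsive genes back toward air was tested with the 5 LPS libraries divided so that none served on both sides (20 splits, median 415.5 genes). The share of these genes that moved toward air was 45.7% with nAAT (range over splits 38.5% to 64.2%), 58.1% with oxAAT (43.6% to 82%) and 45.3% with recAAT (29.3% to 72.3%). Simulated unchanged groups gave 50.5% (48.6% to 53.8% over 20 simulations), 50% (46.4% to 54.3%) and 50.2% (47.6% to 53.3%). There the air and LPS libraries were also drawn, gene by gene, around their group means. They held no GC differences between libraries of a group and no library set, so the simulated ranges do not measure the real spread. The median log2 change in the direction of LPS was 0.04, -0.05 and 0.04. For response genes with an absolute log2 fold change of at least 1 the shares were 37.9% (27.2% to 49.8%), 42.8% (31.2% to 62.7%) and 28.6% (16.8% to 44.5%), and the median changes 0.15, 0.06 and 0.23, away from air. With the set as a term the shares over all response genes were 48.9%, 56.3% and 41.6%. For those with an absolute log2 fold change of at least 1 they were 37.8%, 45.5% and 31.4%.

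Fold changes against LPS were also compared between AAT groups over the 17148 genes, which are not independent replicates. For LPS+oxAAT and LPS+recAAT r was 0.87, against 0.5 simulated with unchanged groups that share the LPS libraries, and the covariance was 0.151 against 0.027 simulated. The simulation drew each gene by itself around its group mean. It held no GC differences between libraries of a group and no library set, so these sources are missing from all simulated values here. With the LPS libraries divided between the comparisons r was 0.52. The 2 groups shared 608 genes called higher and 74 called lower with the LPS libraries shared, a median of 17 and 4 with them divided, and in edgeR 0 and 0 with the set as a term, where LPS+recAAT vs LPS had no call. For LPS+nAAT with LPS+oxAAT r was 0.39 (simulated 0.51) with covariance 0.048 (simulated 0.027), and with LPS+recAAT r was 0.42 (simulated 0.5) with covariance 0.056 (simulated 0.027). Those r were 0.08 and 0.11 with the LPS libraries divided. The called genes shared were 24 higher and 5 lower with LPS+oxAAT (a median of 1 and 1 with the LPS libraries divided, and 1 and 2 with the set as a term) and 42 and 11 with LPS+recAAT (2 and 2, and 0 and 0). With the set as a term r was 0.78 for LPS+oxAAT and LPS+recAAT, and 0.33 and 0.23 for LPS+nAAT with either. Only LPS+oxAAT holds libraries of both sets, so the set is estimated from that group. With the term, the LPS+oxAAT and LPS+recAAT changes therefore both contain the first-set LPS+oxAAT libraries. That raises their r by construction, so 0.78 alone does not show that these preparations act alike.

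The other 18 lists had no camera call in the comparisons of LPS with air and of each AAT group with LPS. They were markers of T cells, NK cells, plasma cells, eosinophils with mast cells and basophils, club cells, ciliated cells, endothelium, fibroblasts, skeletal muscle, fat, red blood cells and platelets, and the glucocorticoid, circadian clock, Nrf2, unfolded protein, PPAR and nuclear non-coding RNA lists. Their lowest adjusted p was 0.055, for the glucocorticoid list in LPS vs air. Of the panel, Il6 (0.21 ± 0.51), Serpina1a, a mouse gene for AAT with close paralogs (0.21 ± 0.47), and Angptl4 (-0.17 ± 0.24) did not pass in LPS vs air, nor in any AAT group against LPS.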

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

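The tests of GC content, of the library set for Nr1d1, of alveolar macrophages and of the hour of death were chosen only after the results were seen, as were the division into library sets that the tests of LPS+recAAT use and the leaving out of LPS+oxAAT libraries in the test of the preparation. Of 209 groups of 5 values tested, 9 (4.3%) held a library far from the others, where chance gives about 1 in 20. These were Pclaf in LPS replicate 1104 (2.44 CPM, nearest other 3.45), mt-Nd6 in LPS replicate 1105 (16.7, 8.11), Tmem252 in LPS+nAAT replicate 4103 (36.7, 33.4), Nr1d1 (111, 87.2) in LPS+recAAT replicate 6103, Sh3d21 (47.2, 33.1) in LPS+recAAT replicate 6102 and Klf10 in LPS+oxAAT replicate 5103 (62.5, 52). In LPS+oxAAT replicate 5105 they were Tmem252 (37.5, 21.7), Csrnp1 (30.2, 19.9) and Errfi1 (154, 105). A difference between groups of libraries was the 93 genes between the LPS+oxAAT libraries of the 2 library sets. A signal outside the comparisons was the detection of up to 57 of 151 genes opposite well expressed genes in the second set, against at most 27 in the first.

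More genes were higher than lower in LPS+recAAT than in LPS (1110 against 346). The difference between the second-set and first-set LPS+oxAAT libraries amounted to 56.7% of the called change, against -46.5% to 22.9% for the other of the 10 choices of 3 of the 5 LPS+oxAAT libraries, so the library set may account for much of it. With the GC curve removed 54.7% of the called genes were higher, so GC content could account for most of the excess of higher genes. With the library set as a term a median of 41.7% of the called change was kept (34.8% to 47.8% with each LPS+oxAAT library left out). The SE rose from 0.12 to 0.19, and 86.8% of the called genes kept their direction. The term is estimated from the same 5 LPS+oxAAT libraries as the 56.7%, so the 41.7% is not a second, independent test. It argues against the recombinant preparation as the whole cause only as far as those 5 mice show the effect of the set. A smaller effect of the preparation stays open, because every LPS+recAAT library is in the second set.

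Cell cycle genes were higher in LPS+nAAT than in LPS. All 10 libraries of these groups lie in the first set, so the library set does not separate them. The median log2 change was 0.6 with the GC curve removed, against 0.64, which argues against GC content as the whole cause. It was 0.57 at the lowest with a single library left out, LPS+nAAT replicate 4102, but of the 25 genes 4 passed without that library or LPS replicates 1101, 1102 or 1104, and 5 and 6 without LPS+nAAT replicates 4103 and 4104. Alveolar macrophages divide in the lung and might be more numerous, and their markers had a median of 0.36 (quartiles 0.25 to 0.51 over 16 genes), but bulk counts cannot assign the cell cycle transcripts to a cell type, so this cannot be told apart from division in other cells. An effect of nAAT stays open as a hypothesis.

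Nr1d1 was lower in LPS+recAAT than in LPS+oxAAT. It was -1.38 within the second library set and -1.58 with the GC curve removed, which argues against library set and GC content. The hour of death might contribute but stays open: within the second set the 5 other clock genes of its phase had a median of -0.25 and 3 of the opposite phase 0.35, a difference of -0.6. None of these 8 passed (adjusted p from 0.378 to 0.935), and Tef (0.03) and Clock (-0.18) went against that pattern. The labels give no hour of death, and an effect of the recombinant preparation on the clock stays open as untested.

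Other splits of the libraries were fitted as 2 groups, with the 3 AAT groups as 1 group for their mean, each counted with the real one included. Where 100 splits are given, they were drawn from 126, or from 15504 for the mean. No other split gave as many genes for LPS vs air (1 of 56 splits, real 354, highest other 1). The same held for LPS+recAAT vs LPS (1 of 100, 1097, 284), the mean of the AAT groups (1 of 100, 910, 3) and LPS+recAAT vs LPS+nAAT (1 of 100, 561, 124). It also held for LPS+nAAT vs air (1 of 56, 919, 2) and LPS+recAAT vs air (1 of 56, 1369, 4). Each of these shares is the smallest the test could give, so chance is unlikely there but not excluded. Few splits also gave as many genes for LPS+nAAT vs LPS (3 of 100; 16, 608), LPS+oxAAT vs LPS (4 of 100; 15, 2819), LPS+recAAT vs LPS+oxAAT (3 of 100; 1, 1291) and LPS+oxAAT vs air (2 of 56; 414, 703), but other splits called more there, so these counts of splits alone do not exclude chance. For LPS+oxAAT vs LPS+nAAT, with the highest share of splits (5 of 100, real 10, highest other 2373), chance cannot be excluded either. For LPS+recAAT vs LPS, vs LPS+nAAT and vs air the real grouping is also that of the library sets, so these counts do not tell the AAT effect from the set. The same limit holds for the mean of the AAT groups, where 8 second-set libraries lie on the AAT side and 0 in LPS. With the set as a term 9 genes passed for the mean. In that fit the first-set LPS+oxAAT libraries weigh most among the AAT libraries. A split that called several times the real count points to a structure of the samples. For LPS+oxAAT vs LPS it placed LPS+oxAAT replicate 5102 with LPS replicates 1101 to 1104. For LPS+oxAAT vs air the split with 703 placed the 2 first-set LPS+oxAAT libraries with air and so followed the library set, and within the first set 251 genes passed. For LPS+nAAT vs LPS the split with 608 parted the libraries by GC content: the rank correlation of transcript GC with the deviation of log2 CPM from the mean of all libraries was 0.38 to 0.66 in LPS replicates 1101, 1102 and 1104 and LPS+nAAT replicates 4101 and 4102, and -0.54 to 0.23 in the other 5. With the GC curve removed 77 genes passed between LPS+nAAT and LPS, against 102 over all libraries without it.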

How the results depend on the processing

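The library set term, the single-set fits and the GC curve were chosen only after the results were seen. Of the 11 counts of genes, all stayed within 1.5 times with DESeq2 size factors, library totals alone, a stricter filter and a dispersion that was not robust. With no filter on low counts 2 moved, LPS+nAAT vs LPS to 50 and LPS+oxAAT vs LPS+nAAT to 25. With 1 surrogate variable LPS+oxAAT vs LPS+nAAT moved to 34.

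An adjusted p under 0.01, stricter by construction, gave 351 for LPS vs air, 9, 154 and 573 for LPS+nAAT, LPS+oxAAT and LPS+recAAT vs LPS, 334 for their mean, 3 and 54 for LPS+oxAAT and LPS+recAAT vs LPS+nAAT, and 542, 372 and 634 for the 3 AAT groups vs air. A fit of only the groups compared, with fewer samples, gave 354 for LPS vs air, 16 and 15 for LPS+nAAT and LPS+oxAAT vs LPS, 10 and 561 for LPS+oxAAT and LPS+recAAT vs LPS+nAAT, 1 for LPS+recAAT vs LPS+oxAAT and 414 for LPS+oxAAT vs air. The DESeq2 Wald test gave 429 and 1255 for LPS+nAAT and LPS+oxAAT vs LPS, 241 and 602 for LPS+oxAAT and LPS+recAAT vs LPS+nAAT and 8 for LPS+recAAT vs LPS+oxAAT. Voom with quality weights gave 40 and 1688, 1073 and 1523, and 12 in that order, and 1766, 1323 and 2312 for the AAT groups vs air. For these 2 tools the cause was not tested.

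With the library set as a term the counts were 196, 6 and 0 for LPS+nAAT, LPS+oxAAT and LPS+recAAT vs LPS, 9 for their mean, 1 and 0 for LPS+oxAAT and LPS+recAAT vs LPS+nAAT, and 336 and 278 for LPS+oxAAT and LPS+recAAT vs air. Each 0 came from edgeR, with 1261 and 2093 genes at an unadjusted p under 0.05. DESeq2 and voom were run only without the term, where DESeq2 called 1930 and 602 and voom 2038 and 1523. In the first set alone, with fewer samples, they were 34 and 13 for LPS+nAAT and LPS+oxAAT vs LPS, 2 for LPS+oxAAT vs LPS+nAAT and 251 for LPS+oxAAT vs air. Removing the GC curve gave 233, 688 and 458 for LPS+oxAAT, LPS+recAAT and the mean vs LPS and 181 for LPS+oxAAT vs LPS+nAAT. With both the GC curve removed and the set as a term they were 7, 0 and 15 vs LPS, 2 and 0 for LPS+oxAAT and LPS+recAAT vs LPS+nAAT, and 392 and 321 for LPS+oxAAT and LPS+recAAT vs air, with 1483 and 2110 genes at an unadjusted p under 0.05 where edgeR called 0. In simulated data of LPS+recAAT vs LPS the set term recovered 50 of 100 genes changed 2-fold and 5 of 100 changed 1.5-fold. Without the term 80 and 41 were recovered, so part of the fall is lost power, and more of it for small changes. The genes called there without the term changed by a median of 0.5 on the log2 scale. For LPS+recAAT vs LPS the test of the library set is given in the part above, and for the other counts the cause was not tested.

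With the last digit of the mouse number as a block 3 counts moved, LPS vs air to 1364, LPS+nAAT vs LPS to 248 and LPS+oxAAT vs LPS+nAAT to 24. Libraries with the same digit had a mean residual correlation of 0.076 over 42 pairs, against -0.019 for the others. Of 23 libraries, 5 were closest on average to those with their own digit, so libraries of a digit may share only a number.

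With each library left out, the lowest and highest counts were 391 (without air replicate 2102) and 904 for LPS vs air, 20 (LPS 1104) and 144 for LPS+nAAT vs LPS, 167 (LPS+oxAAT 5103) and 1881 (LPS+oxAAT 5102) for LPS+oxAAT vs LPS, 865 (LPS 1104) and 2316 (LPS 1105) for LPS+recAAT vs LPS, and 410 (LPS 1104) and 2262 (LPS 1105) for the mean. They were 3 (LPS+oxAAT 5104) and 275 (LPS+oxAAT 5102) for LPS+oxAAT vs LPS+nAAT, 88 (LPS+recAAT 6101) and 282 for LPS+recAAT vs LPS+nAAT, 2 and 4 for LPS+recAAT vs LPS+oxAAT, 655 and 901 for LPS+nAAT vs air, 392 (air 2105) and 785 for LPS+oxAAT vs air, and 762 (air 2105) and 1055 for LPS+recAAT vs air. The cause was not tested.

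Of 188 calls of named genes, 187 were past the threshold in the same direction with DESeq2 size factors and with the DESeq2 Wald test, 186 with library totals, 168 with no filter, 162 with the GC curve removed, 118 with the set as a term and 134 with every library left out in turn, as were 91 of 132 in the first set alone. Syn3 reversed with the set as a term, to -0.25 in LPS+recAAT vs LPS and -0.28 vs LPS+nAAT. Of 37 camera calls, 9 passed with an estimated correlation, 18 with fry, 30 with the set as a term, 31 with the GC curve removed and 30 of 32 in the first set alone. LPS vs air (16 camera calls) and LPS+nAAT vs LPS (10) compare first-set libraries only, so the term could not shift their fold changes. Of the 16 genes the naming rule gave per comparison, 16 and 16 kept their call there with the term. In LPS+oxAAT vs LPS 3 of 16 did, and in LPS+recAAT vs LPS 0 of 16. The mitochondrially encoded genes in LPS+oxAAT vs LPS lost their camera call with the GC curve removed, and the direction of that test turned only at an adjusted p of 0.99. For the B cell markers in LPS+recAAT vs LPS the direction turned with the set as a term (camera adjusted p = 0.067). Neither list passed in the turned direction. The cause was not tested.

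Fold changes in LPS+nAAT correlated with those in LPS+oxAAT and LPS+recAAT at r = 0.08 and 0.11 with the LPS libraries divided, and LPS+oxAAT with LPS+recAAT at 0.52, which by construction removes the shared LPS libraries. With the set as a term and the LPS libraries shared, r was 0.23 for LPS+nAAT with LPS+recAAT and 0.78 for LPS+oxAAT with LPS+recAAT. With both the term and divided libraries these were -0.03 and 0.42. With the term the LPS+oxAAT and LPS+recAAT changes both contain the first-set LPS+oxAAT libraries, so 0.78 and 0.42 are raised by construction. Of LPS-response genes with an absolute log2 fold change of at least 1, 37.9%, 42.8% and 28.6% moved toward air with nAAT, oxAAT and recAAT, and the cause was not tested.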

Other observations

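Of 12 glucocorticoid responsive genes, 4 are given here as values, chosen after the results were seen, while the list had no camera call (adjusted p = 0.57, 0.073 and 0.39 for LPS+nAAT, LPS+oxAAT and LPS+recAAT vs LPS). Zbtb16 was higher than in LPS by log2 fold changes of 3.17 ± 0.61, 2.56 ± 0.60 and 2.13 ± 0.59 (SE) in LPS+nAAT, LPS+oxAAT and LPS+recAAT, and Fkbp5 by 1.57 ± 0.27 and 1.12 ± 0.27 in LPS+nAAT and LPS+recAAT. Per1 was lower in LPS+oxAAT (-1.18 ± 0.19) and LPS+recAAT (-0.85 ± 0.19), as was Errfi1 (-0.86 ± 0.15 and -0.88 ± 0.15). With the library set as a term only Per1 in LPS+oxAAT (-1.54, adjusted p = 0.0127) passed of these calls in LPS+oxAAT and LPS+recAAT. In LPS+nAAT Zbtb16 (0.0177) and Fkbp5 (0.00647) passed with it. All libraries of that comparison lie in the first set, so the term could not shift their fold changes. In the first set alone Fkbp5 passed there (adjusted p = 0.000881) and Zbtb16 did not (0.0523). The direct tests between preparations did not pass for Zbtb16 (LPS+oxAAT vs LPS+nAAT -0.61 ± 0.56, adjusted p = 0.72; LPS+recAAT vs LPS+nAAT -1.04 ± 0.57, 0.415) or Fkbp5 (-0.83 ± 0.26, 0.18; -0.45 ± 0.26, 0.45).

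Insig1, a regulator of cholesterol synthesis, was lower in LPS than in air (-0.81 ± 0.11) and higher in LPS+oxAAT (0.64 ± 0.10) and LPS+recAAT (0.62 ± 0.10) than in LPS. With the library set as a term it passed in LPS+oxAAT (0.73, adjusted p = 0.0145) and not in LPS+recAAT (0.78, 0.229). These comparisons share the LPS libraries, so an error in the LPS mean moves them in opposite directions.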
